A study of Mus musculus with 8 samples.

How the data were processed

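RNA was sequenced from cultures of neonatal mouse cardiac fibroblasts, 4 untreated and 4 treated with TGF-β1. Per the labels' protocols, hearts were digested with collagenase, adherent cells were kept after a short plating step that removes most cardiomyocytes and blood cells, and messenger RNA was enriched with oligo(dT) beads before random-primed library construction. The submitters' processing notes name CASAVA, HISAT2, featureCounts and Subread without versions, and the strand setting of the counting is not given in the sources used here. The deposited table of read counts per gene holds whole numbers for 56748 genes in all 8 libraries and was not normalized. A second deposited table holds FPKM values by the authors, and these equal the count per gene length times a constant for each library. The constant corresponds to a denominator of 0.971 to 1.068 times the library total. Against the library total scaled with the TMM factors used below, it was 1.012 to 1.018 times. How it was chosen is not given in the sources used here. The processing notes name the GRCm38 build and the series design names mm39. The coordinates in the file were compared with annotations of both builds. They overlap the same gene in GRCm39 for 99.9% of matched coding genes and in GRCm38 for 16.0%, so coordinates are given as in the file and read as GRCm39.

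Each library was assigned to its group from the labels. Library totals ran from 14340740 to 17176898 counts. Genes were kept by filterByExpr of edgeR at its default settings (minimum count 10, minimum total 15), which left 13960. Counts were scaled with TMM factors and tested with the edgeR quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with group as the only term, two-sided, and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The biological coefficient of variation was 6.27%. CPM values are counts divided by the TMM-scaled library total, in the usual CPM unit, with the SD over 4 libraries. Standard errors of log2 fold changes were taken as the size of the fold change over the square root of the F statistic, and so carry the moderated spread of the model. Library composition was compared with exact two-sided permutation tests over the 70 assignments of 4 against 4 libraries.

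Gene lists, 29 of pathways and functions and 8 of cell type markers, and the rule for named genes were fixed before the data were examined. The lists were tested with camera at a preset correlation of 0.01, and Benjamini-Hochberg adjustment ran over the 35 lists with a tested member. Of the 21 lists called, 6 were also called with an estimated correlation, namely the TGF-β early targets, the matrix glycoproteins, the resting fibroblast markers, cell division, the p53 targets and complement. The adjusted p also rose for lists whose estimated correlation lay below the preset 0.01. For the BMP and ID genes (estimate −0.035) the camera adjusted p went from 0.00858 to 0.0581. A call lost this way therefore does not by itself show that the members of a list are correlated. The rule named the 8 most raised and 8 most lowered called genes with a CPM of at least 5 in the higher group, no overlap between groups and an established symbol. It also named up to 4 called members of each list with the smallest p (where none was called, the member with the highest CPM), 14 genes always named (among them Acta2, Tagln, Col1a1, Col3a1, Postn, Fn1, Ccn2, Smad7, Tgfb1, Tcf21, Mre11a, Rad50 and Nbn), and the 5 most abundant genes. It gave 160 genes, of which the text describes a part, and 6 of them are not reported here.

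The test was run first on simulated counts for 13960 genes, with the mean levels of the untreated libraries and the library sizes of both groups. With 50 genes at each size, it recovered 48% of those changed by 1.25-fold, 66% at 1.5-fold, 88% at 2-fold and 94% at 4-fold. It also called 13 unchanged genes. Far fewer genes were changed there than were called in the data, which makes the adjusted threshold stricter in the simulation. Replicates were compared in 12 pairs within groups, and the median chi-square per gene lay 2.07 to 3.22 times above sampling noise, so no library was treated as a duplicate. The mean chi-square per gene was 6.23 to 6.73 in the pairs with untreated replicate 1, 2.76 to 3.15 in the other untreated pairs and 3.22 to 5.20 in the TGF-β1 pairs. The spread of each untreated library was taken over genes above 5 on the log2 CPM scale, without ribosomal RNA genes and Lars2. The share of exonic bases under exons of other genes was computed from GENCODE M39.

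The alternatives tried were RLE, upper-quartile and library-total scaling, other count filters, DESeq2 1.42.0, limma on log2 FPKM with pseudocounts of 1 and 0.1, the replicate number as a block, each library left out in turn, and a bound of 1 on the absolute log2 fold change. For the lists, an estimated correlation and fry were tried. A repeat without ribosomal RNA genes and Lars2, and the share of ribosomal RNA as a measure, were added after the data were seen. The Mirin treatment named in the protocol was not analysed here.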

Results

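Gene expression was measured in primary fibroblasts grown from the hearts of 1-day-old C57BL/6J mice. The cells were left untreated or were given transforming growth factor beta 1 (TGF-β1), a cytokine that drives fibroblasts toward the matrix-producing, contractile myofibroblast state, at 10 ng/mL for 48 h. There were 8 libraries of polyadenylated RNA, 4 untreated and 4 treated, and the series design describes the replicates as cultures from different litters. Between 14340740 and 17176898 reads were counted on genes per library, and 20662 to 21295 genes had at least one read. The treatment was meant to model fibrosis in culture, and the comparison asks which transcripts it changed. Untreated replicate 1 stood apart in its ribosomal RNA, which took 0.0332% of its counts (95% exact binomial interval 0.0323% to 0.0342%, counting error only). The share was 2.13% to 2.49% in the other untreated libraries and 1.09% to 2.56% in the treated ones. In untreated replicate 1, other genes of at least moderate level also deviated more from the mean of the remaining untreated libraries. The SD of these deviations was 0.138 on the log2 scale against 0.087 to 0.095 for the other 3.

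TGF-β1 changed 5030 of 13960 tested genes, of which 2451 rose and 2579 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). In the lists of TGF-β feedback genes and matrix glycoproteins 12 of 15 and 12 of 16 members rose, and in the list of cell division genes 28 of 28 fell. The camera calls of these 3 lists held with an estimated correlation (adjusted p = 0.00408, 0.0283 and 0.000166). Most members of the collagen processing (16 of 20), contractile (12 of 16) and fibrillar collagen (6 of 9) lists also rose, but their list calls were lost with an estimated correlation (adjusted p = 0.0581, 0.298 and 0.183). At 2-fold or more, 160 genes rose and 647 fell, 807 in all, against 998 with no count filter and 247 with limma on the log2(FPKM + 1) scale, which understates the change of low genes. Of the genes called, 3478 changed by less than 1.5-fold, and the median size of a called change was 0.34 on the log2 scale. With library totals in place of TMM factors the split was 1301 higher and 3673 lower, and without untreated replicate 1 it was 2155 higher and 2487 lower. In simulated data with the depth and spread of this comparison, 66% of genes changed by 1.5-fold and 88% of those changed by 2-fold were recovered. Small changes were thus missed more often there than large ones. Far fewer genes were changed in the simulation than were called here, so these rates need not hold for the data.

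Direct targets and feedback genes of the TGF-β pathway rose as a group. Of 15 genes in that list, 12 rose and none fell over all genes tested, and 13 rose and 1 fell adjusted over the list alone (camera adjusted p = 6.94e-13, and adjusted p = 0.00408 with an estimated correlation). Ltbp2, which encodes a matrix protein of the latent TGF-β binding family, had the smallest p of all genes (ENSMUSG00000002020, GRCm39 chromosome 12, 84829986 to 84923306, minus strand). Its normalised count went from 143.5 ± 4.70 to 655 ± 20.4 CPM (mean ± SD, n = 4 and 4), a log2 fold change of 2.19 ± 0.04 (SE, edgeR adjusted p = 2.07e-20). Pmepa1, a negative regulator of the pathway, rose by 0.80 ± 0.04. Skil, a SMAD corepressor, rose by 0.76 ± 0.05. Smad7, the inhibitory SMAD, rose by only 0.16 ± 0.04 (edgeR adjusted p = 0.00217), and with library totals its adjusted p was 0.149. Tgfb1 itself rose by 0.34 ± 0.05.

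Ligands, receptors and SMADs of the pathway moved both ways, with 5 of 15 rising and 5 falling (camera adjusted p = 0.273). Ltbp1 rose by 1.61 ± 0.05 and Inhba, an activin subunit, by 0.71 ± 0.04. Inhbb fell by 0.68 ± 0.06 and the type I receptor gene Acvrl1 fell by 0.60 ± 0.05. In the list of BMP and ID genes, 5 of 14 tested members rose and 6 fell, or 5 and 7 adjusted over the list alone (camera, down, adjusted p = 0.00858, and adjusted p = 0.0581 with an estimated correlation). Without untreated replicate 1, 3 rose and 6 fell. In the same comparison of all libraries, 14 of 18 cardiomyocyte markers and 4 of 11 epicardial and mesothelial markers fell. The BMP and ID genes that fell included Bmp4 (log2 fold change −0.88 ± 0.06), Id1 (−0.71 ± 0.05), Id3 (−0.60 ± 0.04) and the inhibitory SMAD gene Smad6 (−0.42 ± 0.04).

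Contractile genes of myofibroblasts rose in 12 of 16 cases and fell in 2 (camera, up, adjusted p = 0.0152, and adjusted p = 0.298 with an estimated correlation). Markers of mural cells, which include contractile smooth muscle, rose in 5 of 7 tested cases and fell in 1 in the same libraries. Their median log2 fold change was 0.84 (camera adjusted p = 2.09e-05, and adjusted p = 0.0587 with an estimated correlation). Myh11, which is in both lists, was not called (−0.07 ± 0.21, edgeR adjusted p = 0.828) at a low level of 2.76 CPM in untreated libraries. Acta2, which encodes smooth muscle α-actin (ENSMUSG00000035783, chromosome 19, 34218490 to 34232990, minus strand), went from 2684 ± 145.1 to 4352 ± 86.6 CPM (SD, n = 4 and 4). This was a log2 fold change of 0.70 ± 0.04 (SE, edgeR adjusted p = 5.53e-13). Tpm1, a tropomyosin, rose by 0.67 ± 0.03 and the myosin light chain gene Myl9 by 0.48 ± 0.04. Mylk, which encodes the kinase that phosphorylates myosin light chain, fell by 1.49 ± 0.06. Tagln, another contractile gene, rose by 0.54 ± 0.12, but from a level of only 8.74 ± 1.48 CPM. Its count is uncertain, because 60.7% of its exonic bases in the GENCODE M39 annotation lie under exons of the antisense gene Gm48529 and the strand setting of the counting is not given in the sources used here.

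**Figure D1:**
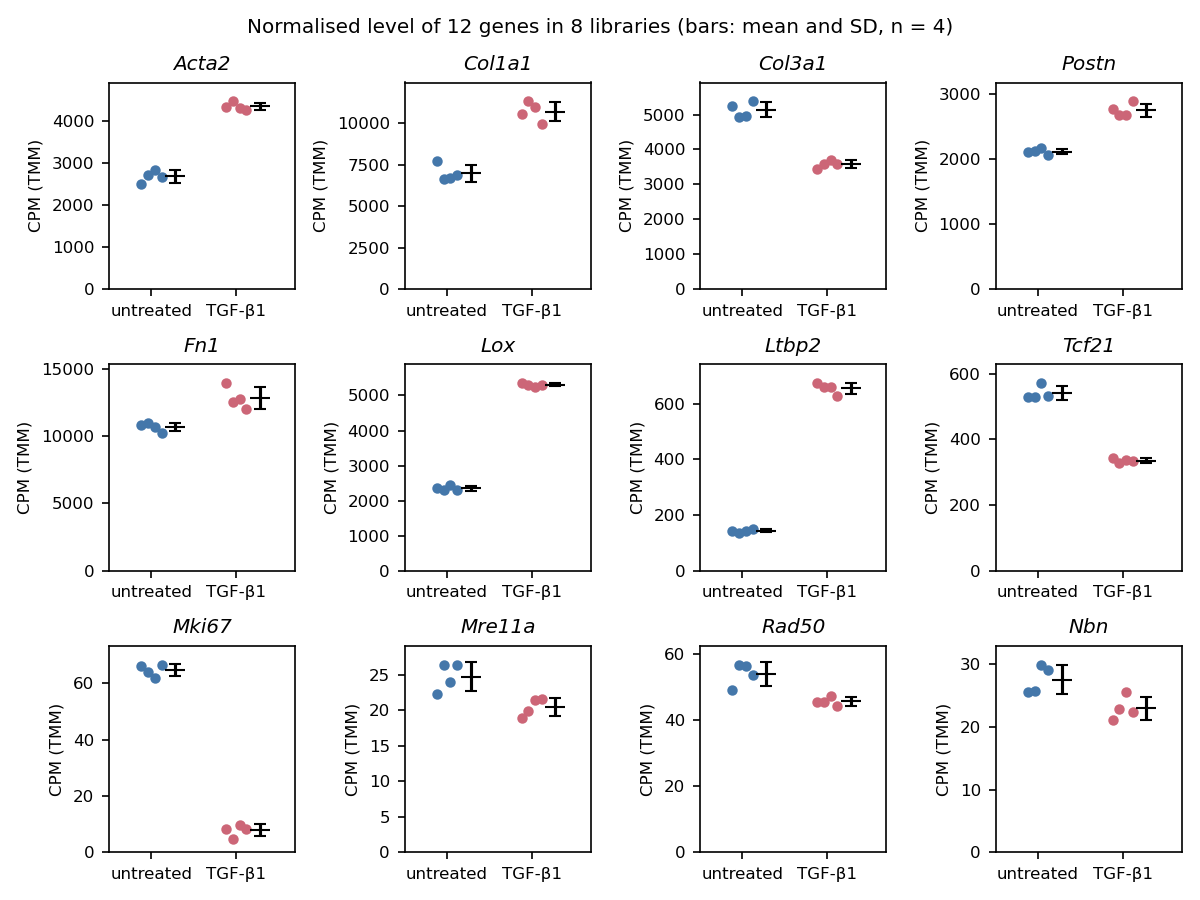
Normalised count (CPM with TMM factors, vertical axis from 0) of 12 genes in each of the 4 untreated and 4 TGF-β1 libraries, with points for libraries and bars for the mean and SD. Acta2, Col1a1, Postn, Fn1, Lox and Ltbp2 lie higher in all treated libraries, and Col3a1, Tcf21, Mki67, Mre11a, Rad50 and Nbn lie lower.

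Fibrillar collagens rose in 6 of 9 cases and fell in 1 (camera, up, adjusted p = 0.000144, and adjusted p = 0.183 with an estimated correlation). Col1a1, the α1 chain of type I collagen, went from 6974 ± 521.4 to 10700 ± 595.9 CPM (SD, n = 4 and 4), and its log2 fold change was 0.62 ± 0.04. Col11a1 rose by 1.61 ± 0.04 and Col5a2 by 0.84 ± 0.03. Col3a1, the chain of type III collagen, fell from 5132 ± 213.4 to 3572 ± 115.3 CPM (SD, n = 4 and 4), a log2 fold change of −0.52 ± 0.03 (SE, edgeR adjusted p = 2.69e-11). Col3a1 and Col5a2 lie next to each other on chromosome 1, at 45350698 to 45388866 on the plus strand and 45413481 to 45542442 on the minus strand, and they moved in opposite directions.

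Enzymes that process and crosslink collagen rose in 16 of 20 cases and fell in 3 (camera, up, adjusted p = 2.84e-08, and adjusted p = 0.0581 with an estimated correlation). Lox, the lysyl oxidase, rose from 2353 ± 67.3 to 5304 ± 47.1 CPM (SD, n = 4 and 4), or by 1.17 ± 0.03 on the log2 scale. Its relative Loxl2 rose by 0.67 ± 0.04, the lysyl hydroxylase gene Plod2 by 0.63 ± 0.03 and the procollagen protease gene Bmp1 by 0.57 ± 0.04.

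Matrix glycoproteins of fibrosis rose in 12 of 16 cases and fell in 4 (camera, up, adjusted p = 6.09e-10, and adjusted p = 0.0283 with an estimated correlation). The 4 that fell were Tnc (−0.41 ± 0.05), Thbs2 (−0.36 ± 0.03), Eln (−0.19 ± 0.05) and Fbn2 (−0.17 ± 0.06). The secreted protein gene Cthrc1 rose by 1.58 ± 0.07, Col12a1 by 1.47 ± 0.04 and the proteoglycan gene Vcan by 1.11 ± 0.05. Ccn2, a matricellular protein gene, rose by 1.00 ± 0.04. Postn, encoding periostin, rose by 0.38 ± 0.03. Fn1, encoding fibronectin, rose by 0.26 ± 0.04 from 10690 ± 317.8 CPM (SD, n = 4), and Sparc rose by 0.11 ± 0.03 from 10850 ± 544.3 CPM (SD, n = 4). The Sparc call was lost with library totals (edgeR adjusted p = 0.466), with limma on log2(FPKM + 1) and log2(FPKM + 0.1) (adjusted p = 0.105 and 0.094) and without untreated replicate 4 (edgeR adjusted p = 0.0557). Of the mural cell markers, 5 of 7 tested also rose in the treated libraries, while Kcnj8, Abcc9 and Higd1b did not pass the count filter. Whether the rise of mural markers is linked to those of the fibrillar collagen, collagen processing and matrix glycoprotein lists was not tested.

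The other 4 matrix and adhesion lists were not called by camera, which compares a list with other genes. The rotation test fry, which asks whether the members of a list move one way on balance, gave each a direction. In basement membrane genes 4 of 18 rose and 8 fell (camera adjusted p = 0.235, and fry, down, adjusted p = 0.00886), with Lama2 at 0.60 ± 0.04 and Nid2 at −0.93 ± 0.04. Matrix proteases and their inhibitors rose in 6 of 15 cases and fell in 7 (camera adjusted p = 0.549, and fry, down, adjusted p = 0.0157). The inhibitor gene Timp1 rose by 0.60 ± 0.05, whereas Timp2 fell by 0.52 ± 0.03 and the protease genes Mmp3 and Mmp12 fell by 2.46 ± 0.18 and 2.30 ± 0.21. Genes of cartilage and tendon rose in 5 of 11 cases and fell in 4, with a median of 0.18 while the direction was down in camera (adjusted p = 0.549) and in fry (adjusted p = 0.028). The aggrecan gene Acan rose by 2.39 ± 0.23 and the tendon transcription factor gene Scx by 1.03 ± 0.09, and the small proteoglycan gene Fmod fell by 1.68 ± 0.06. Integrin and focal adhesion genes rose in 12 of 23 cases and fell in 5 (camera adjusted p = 0.269, and fry, up, adjusted p = 0.0067). Itga5, a fibronectin receptor subunit, rose by 0.53 ± 0.04 and Itga8 fell by 0.80 ± 0.05.

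Markers of resting cardiac fibroblasts fell in 11 of 16 cases and rose in 3, with a median log2 fold change of −0.74 (camera, down, adjusted p = 1.92e-11, and adjusted p = 0.00408 with an estimated correlation). Tcf21, a transcription factor of the fibroblast lineage, went from 540.3 ± 21.1 to 335.5 ± 6.37 CPM (SD, n = 4 and 4), a log2 fold change of −0.69 ± 0.04. Pdgfra, encoding the platelet-derived growth factor receptor α, changed by −1.18 ± 0.05, Hsd11b1 by −1.11 ± 0.04, Dpt by −0.96 ± 0.04 and Abca8a by −1.80 ± 0.06. The 3 that rose were Mfap4 (0.91 ± 0.05), Dpep1 (0.60 ± 0.05) and Gfpt2 (0.29 ± 0.04). Other cell type markers also moved in these libraries, with cardiomyocyte and epicardial and mesothelial markers called down and mural markers called up (camera adjusted p = 1.64e-06, 0.00599 and 2.09e-05). None of these calls held with an estimated correlation (camera adjusted p = 0.0551, 0.0581 and 0.0587). Of 18 cardiomyocyte markers, 14 fell and none rose, or 15 fell adjusted over the list alone (camera adjusted p = 0.0551 with an estimated correlation). Tnnt2, the cardiac troponin T gene, went from 518.4 ± 22.9 to 297.5 ± 29.2 CPM (SD, n = 4 and 4), and Myh6 changed by −0.81 ± 0.07.

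Complement genes fell in 7 of 10 cases and rose in 1, with a median of −1.02 (camera, down, adjusted p = 2.91e-08, and adjusted p = 0.0131 with an estimated correlation). Serping1, which encodes an inhibitor of the cascade, changed by −1.20 ± 0.04, and the C1 protease genes C1ra and C1s1 by −1.29 ± 0.09 and −2.42 ± 0.14. Adipogenic and lipid handling genes fell in 5 of 13 cases and rose in 1 (camera, down, adjusted p = 0.00599, and adjusted p = 0.109 with an estimated correlation). Lpl, the lipoprotein lipase gene, fell by 1.18 ± 0.04. Of the NADPH oxidase and antioxidant genes, 2 of 19 rose and 7 fell (camera, down, adjusted p = 0.0107, and adjusted p = 0.0581 with an estimated correlation). Nox4, a source of hydrogen peroxide, rose by 0.80 ± 0.09, and the extracellular superoxide dismutase gene Sod3 fell by 1.05 ± 0.05. Gpx3 fell by 0.84 ± 0.05, with 85.0% of its exonic bases under exons of other genes in GENCODE M39, so that its count is uncertain. Cardiomyocyte markers were also lower in the treated libraries. Their median level was 7.19 CPM over all libraries, with Tnnt2 at 518.4 CPM in untreated ones. Whether their fall is linked to the falls of these 3 lists was not tested.

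Cell division genes fell in 28 of 28 cases, with a median log2 fold change of −2.48 (camera, down, adjusted p = 2.17e-99, and adjusted p = 0.000166 with an estimated correlation). Mki67, the proliferation antigen Ki-67 (ENSMUSG00000031004, chromosome 7, 135291513 to 135318090, minus strand), went from 64.6 ± 2.16 to 7.86 ± 2.08 CPM (SD, n = 4 and 4). Its log2 fold change was −3.04 ± 0.10 (SE, edgeR adjusted p = 9.56e-16). Top2a, Tpx2 and Cdk1 changed by −2.88 ± 0.08, −2.45 ± 0.08 and −2.31 ± 0.07. Among the 8 most strongly lowered genes that met the naming rule, Cenpf (−3.27 ± 0.14), Nuf2 (−3.30 ± 0.20), Cdc6 (−3.24 ± 0.21) and Pbk (−3.18 ± 0.21) act in DNA replication or mitosis. The lowest of the 8, Fgl2, a fibrinogen-like protein gene, fell from 46.1 ± 9.02 to 4.31 ± 0.48 CPM (SD, n = 4 and 4). Cyclin-dependent kinase inhibitors and D cyclins had no common direction, with 4 of 13 rising and 6 falling, or 4 and 7 adjusted over the list alone (camera adjusted p = 0.9). Their median was −0.12 while the camera direction was up. Cdkn2b and Cdkn2a rose by 1.68 ± 0.04 and 1.62 ± 0.12, Cdkn2c fell by 1.63 ± 0.11 and Ccnd1 fell by 0.90 ± 0.07.

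The genes of the MRE11-RAD50-NBN (MRN) complex, which senses DNA double-strand breaks, were of interest because the treatment protocol also names an inhibitor of this complex, although no library analysed here is labelled with it. All 3 fell slightly. Mre11a (ENSMUSG00000031928, chromosome 9, 14695950 to 14748419, plus strand) went from 24.8 ± 2.04 to 20.4 ± 1.24 CPM (SD, n = 4 and 4), a log2 fold change of −0.28 ± 0.08 (SE, edgeR adjusted p = 0.00726). Rad50 changed by −0.24 ± 0.06 (edgeR adjusted p = 0.00163) and Nbn by −0.26 ± 0.08 (edgeR adjusted p = 0.00981). In the full list of double-strand break repair genes, 19 of 29 fell and 2 rose, or 20 and 3 adjusted over the list alone (camera, down, adjusted p = 9.26e-06, and adjusted p = 0.0581 with an estimated correlation). Without untreated replicate 1, 18 fell and none rose. Among the named members, Brca1 (−2.18 ± 0.17), Fancd2 (−2.51 ± 0.23) and the helicase gene Blm (−1.69 ± 0.16) fell. Cell division genes and cardiomyocyte markers fell in the same libraries.

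Targets of p53 rose in 13 of 18 cases and fell in 1, or in 14 and 1 adjusted over the list alone (camera, up, adjusted p = 1.42e-05, and adjusted p = 0.0347 with an estimated correlation). Perp rose by 1.07 ± 0.06, Plk2 by 0.59 ± 0.05, the cell cycle inhibitor gene Cdkn1a by 0.45 ± 0.04 and Ccng1 by 0.43 ± 0.03. Genes of cGAS-STING signalling and the interferon response fell in 19 of 28 cases and rose in 1, or in 22 and 1 adjusted over the list alone (camera, down, adjusted p = 0.000759, and adjusted p = 0.298 with an estimated correlation). Without untreated replicate 1, 21 fell and none rose, and 14 of 18 cardiomyocyte markers fell in the same comparison of all libraries. Sting1, the adaptor of cytosolic DNA sensing, fell by 0.59 ± 0.08. Irf7 changed by −0.52 ± 0.08, Ifit2 by −0.57 ± 0.06 and Ifi27l2a by −0.63 ± 0.07.

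Cytokine and chemokine genes were divided, with 7 of 14 rising and 6 falling (camera, up, adjusted p = 4.77e-05, and adjusted p = 0.0581 with an estimated correlation). Cx3cl1, encoding fractalkine, rose from 13.5 ± 0.90 to 71.4 ± 2.30 CPM (SD, n = 4 and 4). Ptgs2, the inducible cyclooxygenase gene, rose by 1.90 ± 0.11 and Cxcl12 by 1.12 ± 0.04, and the monocyte attractant gene Ccl2 fell by 1.35 ± 0.08. The strongest increases among genes that met the naming rule were those of Sfn (4.20 ± 0.31), Ntrk2 (4.08 ± 0.25) and the retinoic acid binding protein gene Crabp2 (3.13 ± 0.18), all from 1.12 CPM or less in untreated cells.

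Targets of YAP-TEAD and SRF rose in 10 of 18 cases and fell in 2 (camera, up, adjusted p = 0.00107, and adjusted p = 0.0581 with an estimated correlation), with Nuak2 at 0.84 ± 0.06, Ccn1 at 0.62 ± 0.06 and Ankrd1 at 0.50 ± 0.04. Wnt pathway genes rose in 8 of 18 cases and fell in 8, or 9 adjusted over the list alone (camera adjusted p = 0.269). The secreted antagonist gene Sfrp2 fell by 2.21 ± 0.08 and the ligand gene Wnt9a rose by 1.09 ± 0.08. Transcription factors of fibroblast activation rose in 6 of 25 cases and fell in 9, or in 6 and 11 adjusted over the list alone (camera, up, adjusted p = 0.9, with a median of −0.09). Runx1 rose by 1.66 ± 0.06 and Meox1 by 1.58 ± 0.13.

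Genes of amino acid synthesis and targets of ATF4 rose in 16 of 18 cases and fell in 2 (camera, up, adjusted p = 1.05e-05, and adjusted p = 0.0739 with an estimated correlation). Trib3 rose by 0.72 ± 0.06, the amino acid transporter genes Slc7a5 and Slc7a1 by 0.55 ± 0.04 and 0.42 ± 0.04, and the folate enzyme gene Mthfd2 by 0.44 ± 0.04. Folding genes of the endoplasmic reticulum rose in 13 of 18 cases and none fell, with 14 rising adjusted over the list alone (camera, up, adjusted p = 0.00107, and adjusted p = 0.0581 with an estimated correlation). The chaperone genes Hyou1 and Hspa5 rose by 0.44 ± 0.04 and 0.26 ± 0.03. Glycolysis genes rose in 8 of 17 cases and fell in 1, or in 9 and 1 adjusted over the list alone (camera adjusted p = 0.0834), with Hk2 at 0.56 ± 0.05. Without untreated replicate 1, 5 of them rose and 1 fell. Nuclear-encoded respiratory chain genes rose in 6 of 20 cases and none fell (camera adjusted p = 0.181), and without untreated replicate 1 the number that rose was 2. Cholesterol synthesis genes rose in 2 of 19 cases and fell in 11, or 12 adjusted over the list alone (camera adjusted p = 0.235), with Lss at −0.26 ± 0.04.

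Of the other cell type markers, those of mural cells (pericytes and smooth muscle) rose in 5 of 7 tested cases and fell in 1 (camera, up, adjusted p = 2.09e-05, and adjusted p = 0.0587 with an estimated correlation). The list had 10 members, and Kcnj8, Abcc9 and Higd1b did not pass the count filter (0.12, 0.59 and 0.05 CPM without TMM factors in untreated libraries). On that scale Rgs5 had 0.77 CPM and Pdgfrb 1033 CPM. Which cells gave these transcripts was not tested. Cspg4 rose by 1.60 ± 0.08, Rgs4 by 1.81 ± 0.14 and Mcam by 0.84 ± 0.04, and Notch3 fell by 0.57 ± 0.06. Epicardial and mesothelial markers rose in 2 of 11 cases and fell in 4 (camera, down, adjusted p = 0.00599, and adjusted p = 0.0581 with an estimated correlation), with Upk3b at −0.92 ± 0.05 and Krt19 at −2.13 ± 0.12. Endothelial markers rose in 3 of 10 cases and fell in 2, with a median of −0.09 and the camera direction up (adjusted p = 0.9). With library totals the rises of Cdh5 and Flt1 lost their calls (edgeR adjusted p = 0.0715 and 0.182). Macrophage markers rose in 1 of 12 cases and fell in 3 (camera adjusted p = 0.549). The rise, that of Adgre1, lost its call under several alternatives, such as without TGF-β1 replicate 4 (edgeR adjusted p = 0.0913). Of the Schwann cell markers 3 were tested and none was called (camera adjusted p = 0.975). Their median was −0.12 while the camera direction was up. No erythroid or lymphocyte marker passed the count filter. Apart from the lists for which a separate number is given, counts adjusted over the list alone were the same as those over all genes.

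**Figure D2:**
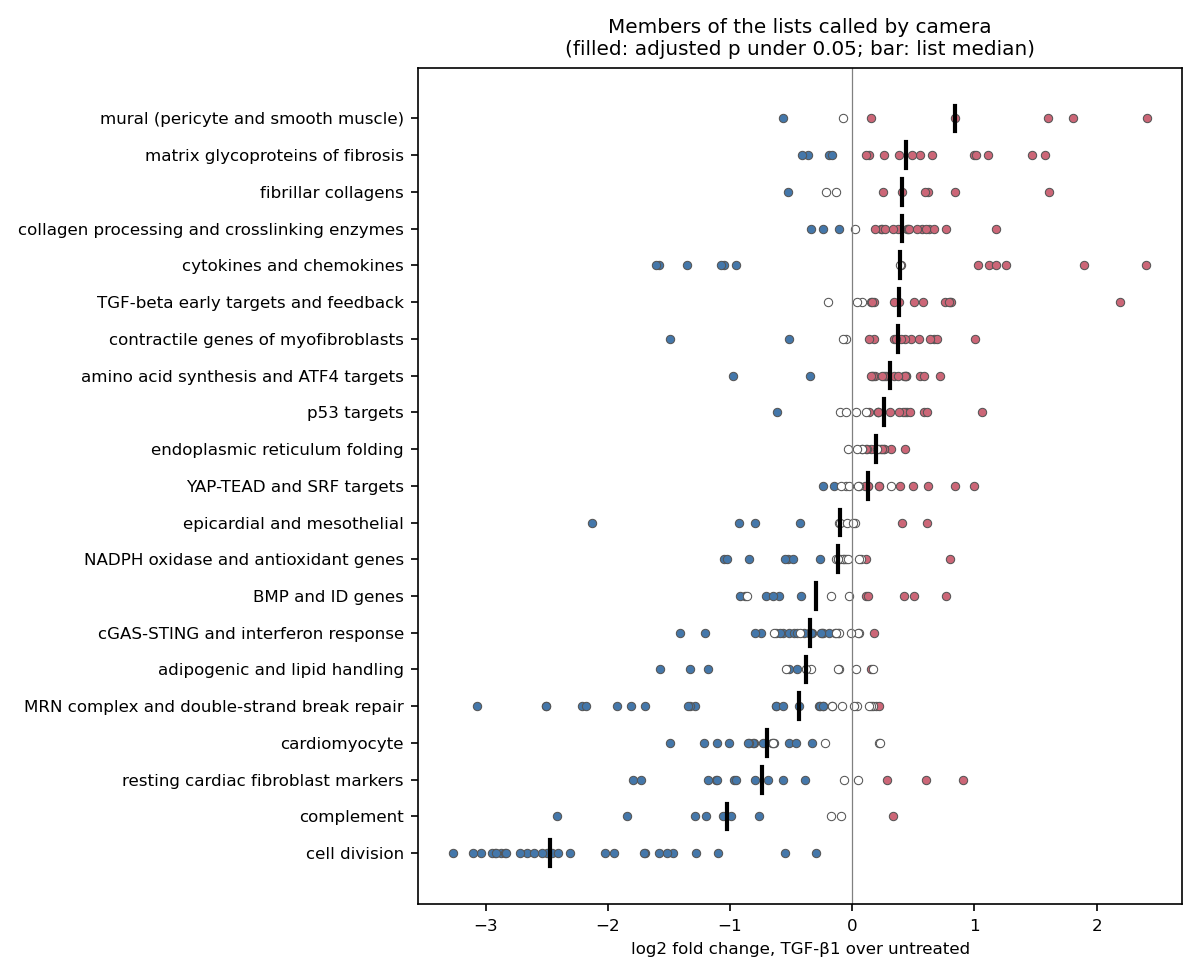
Log2 fold change (TGF-β1 over untreated, horizontal axis) of each tested member of the 21 gene lists that camera called with its preset correlation, one list per line, with filled points for genes with an edgeR adjusted p under 0.05 and a black bar for the list's median. Cell division genes lie furthest to the left, with a median of −2.48.

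The 20 most abundant genes took 11.5% ± 0.96 of the counts in untreated and 13.0% ± 0.54 in treated libraries (SD, n = 4 and 4), and every treated library (12.45% to 13.7%) lay above every untreated one (10.1% to 12.2%). The exact two-sided permutation p of this difference was 0.0286, the smallest that 4 against 4 can give, and 0.143 after Benjamini-Hochberg adjustment over 5 measures, which a single measure cannot bring under 0.05 in this design. Mitochondrially encoded genes took 1.30% ± 0.13 and 1.28% ± 0.12 of the counts (exact permutation p = 0.886, n = 4 and 4), and ribosomal protein genes 3.39% ± 0.14 and 3.48% ± 0.06 (exact permutation p = 0.257, n = 4 and 4). Without untreated replicate 1 the difference in ribosomal protein genes went from 0.096 to 0.028 percentage points and that of the 20 most abundant genes from 1.45 to 0.97. These 20 include the ribosomal RNA gene Rn18s-rs5, which was nearly absent from untreated replicate 1. The low share of 10.1% in that library and the change to 0.97 therefore carry its low ribosomal RNA. Without that library the difference in ribosomal RNA itself went from 0.062 to −0.511 percentage points. Library totals (exact permutation p = 0.6) and genes detected (exact permutation p = 0.171; difference −246, or −382.6 without TGF-β1 replicate 4) had larger p-values as well. The most abundant transcript counted, the ribosomal RNA gene Rn18s-rs5, had a log2 fold change of 0.11 ± 0.57 (edgeR adjusted p = 0.902). Its direction rests on single libraries, since it was −0.30 without untreated replicate 1, which had 305.1 CPM against 20130 CPM or more in the other untreated libraries, and −0.12 without TGF-β1 replicate 1. The value is also uncertain because how reads from copies of this gene were counted is not given in the sources used here.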

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

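The tests of untreated replicate 1 were chosen after its ribosomal RNA was seen, and the count of splits was planned. Of 332 groups of 4 libraries examined, over named genes and composition measures, 14 held one library whose gap to its nearest neighbour, as a share of the range of the group, passed the 95% critical value of Dixon's test. Chance gives about 1 in 20, or 16.6 here.

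The number of genes called was set against that of other groupings of the same libraries. The real split gave 5030 genes by edgeR, and 1 of the 35 splits of the 8 libraries into 4 and 4 gave as many, the real one. The highest of the others gave 0. Every other split mixes treated and untreated libraries, so the treatment difference widens its spread and few calls were likely there. That only the real split gave as many calls makes chance unlikely for this count but does not exclude it.

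Low ribosomal RNA in untreated replicate 1. Ribosomal RNA took 0.0332% of the counts there against 2.13% in the next lowest untreated library (gap 0.857 of the range), and Rn18s-rs5 had 305.1 CPM against 20130 CPM (0.85). Nuclear ribosomal RNA was 69.6-fold and mitochondrial ribosomal RNA 80.0-fold higher in the mean of the other untreated libraries, and Lars2 158.4-fold. Mitochondrial messenger RNAs shifted by a median of −0.24 (log2; −0.2362), below each of the other untreated libraries (−0.179 to 0.103), against −6.32 for mitochondrial ribosomal RNA. This argues against fewer mitochondria as the cause of the fall in ribosomal RNA, and whether they explain the small shift of the messenger RNAs was not tested. Outside ribosomal RNA genes and Lars2, 2 of 10666 genes with at least 5 CPM were 4-fold or more lower there, which is consistent with ribosomal RNA having been removed in the preparation or read filtering of that library, as a hypothesis. Its other genes also deviated more, with an SD of 0.138 (log2) against 0.087 to 0.095 in the other untreated libraries, so the difference of that library is not confined to ribosomal RNA, and the cause of this wider spread was not tested. An earlier form of this test also bounded the median shift of all other genes (0.00116) and was set aside after it was run, because TMM scaling fixes that median near 0. Both genes, ENSMUSG00002076173 and ENSMUSG00002075524, were picked after their values were seen, and no biological explanation other than fewer mitochondria was tested.

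The other values set apart were these. Tgfb1 was lowest in untreated replicate 1, at 55.3 CPM against 60.7 CPM for its neighbour (0.966). In untreated replicate 2, Slc16a3 was highest at 33.2 CPM against 28.1 CPM (0.94) and Flt1 at 32.8 CPM against 29.4 CPM (0.886). Tcf21 was highest in untreated replicate 3, at 571.9 CPM against 530.9 CPM (0.938), and Pimreg lowest there, at 7.82 CPM against 13.1 CPM (0.831). Actn1 was highest in untreated replicate 4, at 789.3 CPM against 774.7 CPM (0.973). Meox1 was lowest in TGF-β1 replicate 1, at 11.6 CPM against 15.3 CPM (0.849). Tpx2 was highest in TGF-β1 replicate 2, at 9.26 CPM against 7.69 CPM (0.901), and Fancd2 in TGF-β1 replicate 3, at 1.62 CPM against 0.78 CPM (0.923). In TGF-β1 replicate 4, Acvrl1 was lowest at 111.1 CPM against 127.3 CPM (0.844), Pbk highest at 2.03 CPM against 0.91 CPM (0.929), and the library total highest (0.915).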

How the results depend on the processing

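The number of genes called stayed within 1.5 times of 5030 under each alternative except a bound of 1 on the absolute log2 fold change, which by construction left 807. That 2-fold count was 998 with no count filter and 247 with limma on log2(FPKM + 1). The number of all genes called ranged from 4517 to 4750 with each library left out in turn (fewer samples), was 4484 with DESeq2 and 4370 with limma on log2(FPKM + 1), and 5056 without ribosomal RNA genes and Lars2, an alternative added after the data were seen. Library totals gave 4974 genes, kept 3880 of the main calls and shifted the median of all genes by −0.08 (log2). The replicate number as a block gave 4971 genes and 21 lists. The labels do not say that a number marks a shared litter, and deviations of same-numbered libraries correlated at −0.12, −0.09, 0.01 and 0.09 over 7937 genes, with 1 of 4 correlating best with its own number. Of 2767 values of 154 named genes under alternatives, 2735 kept their direction and side of the threshold, 29 lost their call (11 genes), 1 gained one and 2 changed sign (1 gene). Most of these genes were named for a small p or a large change in the same libraries, which favours their stability. Of all genes called, 77.1% kept their call with library totals and 83.2% with limma on log2(FPKM + 1). With each library left out in turn, 86.5% to 88.9% did.

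Camera called 21 lists under library totals, the block, and each library left out but TGF-β1 replicate 4 (22, adding glycolysis). With an estimated correlation it called 6, all among the 21; fry, which does not compare a list with other genes, called 30, adding ligands, integrins, glycolysis and the respiratory chain (up) and basement membrane, proteases, cartilage, Wnt and cholesterol genes (down). The calls lost among named genes were those of Adgre1, Cdh5, Flt1, Uqcrc1, Ndufs1, Smad7, Ndufv2, Uqcrc2, Eef1a1, Sparc and Lyz2. Rn18s-rs5, which was not called, changed sign when untreated replicate 1 or TGF-β1 replicate 1 was left out: it ran from −0.30 (without untreated replicate 1) to 0.33, and was called without a count filter (0.12, edgeR adjusted p = 0.000715). Differences in composition (TGF-β1 minus untreated) ran from −0.511 to 0.306 percentage points for ribosomal RNA (−0.511 without untreated replicate 1), from −0.076 to 0.0267 for mitochondrially encoded genes, from 0.028 to 0.13 for ribosomal protein genes, from 0.97 to 1.68 for the 20 most abundant genes, from −382.6 to −181.2 for genes detected, and from −300100 to 755400 for library totals. The adjusted test of composition could not pass for a single measure at this number of libraries, so it says nothing about stability. The 20 most abundant genes include the ribosomal RNA gene Rn18s-rs5, so their share moves with that of ribosomal RNA. The causes of these changes were not tested. In simulation at this depth, spread and number of libraries, 66% of genes changed by 1.5-fold were recovered, and depth was not varied. Far fewer genes were changed in that simulation than were called in the data.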

Other observations

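The tests named here were chosen after the data were seen, except the count of splits for gene lists and the test with library totals. Transcription factor families, as the deposited annotation assigns them, were tested with camera in 17 families of at least 8 tested genes. The E2F family, regulators of entry into DNA synthesis, was lower after TGF-β1, with 5 of 10 members falling and none rising (camera adjusted p = 0.0187, and adjusted p = 0.25 with an estimated correlation). In the IRF family of interferon regulators 7 of 8 members fell and none rose (camera adjusted p = 0.106). Only the E2F family passed the adjustment, and only with the preset correlation.

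The number of gene lists called is a weak measure in this design. The real grouping gave 21 lists by camera with its preset correlation, and 2 of the 35 splits of the 8 libraries into 4 and 4 gave as many, the real one included. The highest of the others gave 22, so chance is not excluded for this count. Splits that put 3 libraries of one treatment together with 1 of the other carry part of the treatment difference, and the other split with as many lists was of this kind. No gene was called by edgeR in any of the other splits.

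Fall of double-strand break repair genes. The tested genes of this list fell with a median log2 fold change of −0.43, which lay 0.44 below the median of all tested genes (difference −0.4396). None of 10000 random sets of 29 genes of like level lay as low (lowest −0.37). A shifted normalization total moves every gene alike, so this argues against it for the list as a whole, but not for each member. A planned test with library totals (median −0.51) was set aside after it was run, because that scaling lowers every gene by the same amount. The list was also divided, after its values were seen and by no rule independent of them, into 13 members that act mainly in replicating cells (median −1.81) and 16 others (median −0.13, with 6 falling and 2, Xrcc5 and Xrcc6, rising). This division therefore tests nothing, and a smaller share of dividing cells and a direct effect of TGF-β1 on these genes, Mre11a, Rad50 and Nbn included, cannot be told apart here. The distance to all genes was not tested for the 16 others alone, so the point on a shifted total does not cover them.

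Narrow spread between libraries. The biological coefficient of variation between replicates was 6.27%. Xist and 4 Y-linked genes were both present in all 8 libraries, at 230.7 to 282.1 and 111.9 to 132.8 CPM, so each culture held cells of both sexes. The log2 ratio of Y-linked genes to Xist had an SD of 0.08 (0.0769) over the 8 libraries, below the 95th percentile of 0.50 for random pairs of autosomal genes of like level. That percentile includes any response of the drawn genes to TGF-β1. It also comes from pairs of single genes, whereas the Y-linked value sums 4 genes, which can narrow its ratio. Within groups the ratio's SD of 0.05 was at percentile 8.13 of random pairs, with the same mismatch. The ratio was higher in every treated library (−1.087 to −0.974) than in every untreated one (−1.196 to −1.093), so it was not even across the groups. One shared pool of cells may account for the even ratio within groups, although the series design describes the replicates as cultures from different litters. Cultures that each combine many pups may account for it too, and the data do not separate these readings. If the pool was shared, the p-values measure the spread between wells and not between litters.

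Some familiar genes had low counts. Gapdh had 5.02 CPM in untreated and 7.67 CPM in treated libraries, whereas the glycolytic genes Aldoa and Pkm had 708.9 and 1155 CPM in untreated libraries. Tagln had 108 to 223 counts per library, against a median of 72.6 CPM for the 15 other contractile genes and 10.7 CPM for Tagln. In the file Tagln spans 45840917 to 45847356 on chromosome 9 and the antisense Gm48529 spans 45841410 to 45845036 (GRCm39). These genes were picked after their values were seen.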
